A study of Mus musculus with 4 samples.

How the data were processed

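Single-cell RNA was measured in 4 libraries of sorted cells from mouse embryos at E10.5, staged at 34 to 36 somites. Of these, 2 libraries came from control embryos carrying Pax2-Cre and a Rosa26-GFP reporter, and 2 from embryos of the same make-up with both floxed alleles of Tbx2 and Tbx3 (conditional knockout, cKO). Per the labels' protocols, the otic vesicle, the cochleovestibular ganglion and adjacent neural tube and pharyngeal tissue were dissected, digested with trypsin and DNase, and sorted for GFP-positive, DAPI-negative cells before droplet capture with the Chromium Next GEM Single Cell kit. The same protocols name 3 control and 2 cKO embryos and state that vesicles were pooled, without saying how embryos were divided among libraries. The labels give no date, run or batch, and no sex of the embryos.

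The deposited matrices hold raw UMI counts of 32285 genes for barcodes already called as cells. Per the file headers, the matrices were written by Cell Ranger 6.0.1, whereas the submitters' processing notes name Cell Ranger 3.1.0, with FastQC 0.11.4, Seurat 4.1.0 and the mouse build mm10. No normalization, doublet removal or cell annotation is part of the deposited counts. Gene positions were taken from the GENCODE vM21 annotation of mm10, in which 32235 of the gene identifiers were found (99.8%).

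Cells with at least 1000 detected genes and at most 10% mitochondrial UMIs passed the cell filter. Doublet scores came from Scrublet as implemented in scanpy 1.11.5. Its automatic threshold called only 3, 2, 5 and 0 cells in the control 1, control 2, cKO 1 and cKO 2 libraries, so the highest-scoring share of each library was removed, at 0.8% per 1000 barcodes, as planned. The control 1 library went from 4800 barcodes to 3869 kept cells, control 2 from 5340 to 3597, cKO 1 from 4622 to 3220 and cKO 2 from 4805 to 3713. The removed doublets numbered 154, 160, 124 and 148 in the same order. A total of 14399 cells was kept.

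For clustering only, counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes among those found in at least 20 cells were reduced to 30 principal components. A graph of 20 nearest neighbours was clustered with leidenalg 0.10.2 at resolution 1, giving 32 clusters, with 0.5 and 2 as alternatives. Of 14 cell classes with fixed marker lists, a cluster took the class with the most supporting markers, each at 10 CPM or more and at least 2 times the median cluster. At least 3 markers and 40% of the list had to support it. Clusters that met the bar for epibranchial neurons or neural tube progenitors were not given to the placodal neuron lineage, whose markers they share. Clusters with a median UMI count under 33.3% of that of all cells stayed unnamed, as did those whose 10 leading genes, found in at least 10% of cells, held more markers of another class than of their own. The marker lists were fixed beforehand, but this naming rule was settled after the clusters had been seen. Of the marker classes, 10 were found. Class names mean resemblance to these markers, since the sort held Pax2-Cre lineage cells and no further label was available.

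Counts were summed per library over all kept cells and over each class with at least 20 cells in every library, so that libraries and not cells were the replicates. Genotypes were compared in R 4.3.3 with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood fit and test, prior count 1) and Benjamini-Hochberg adjustment at 0.05. Every adjusted p for a gene, a class share or a cluster share comes from this test, and all tests are two-sided unless stated. CPM values, UMI counts relative to the library total, are scaled by the TMM factors and given as mean ± SD over n = 2 libraries. In the leukocyte background check, and for Tbx2 and Tbx3 in single clusters, they are instead per total UMI. Log2 fold changes are cKO over control, with standard errors (SE). The otic and neuron lineage responses were compared through a genotype by class interaction with the library as a block. Class shares were tested on cell numbers with the total as offset. An exact permutation test of 2 against 2 libraries cannot give a p below 0.333, so none was used, and groups fail to overlap by chance in 33.3% of genes. Because each group has 2 libraries, p-values measure the spread between these libraries, which may be partly technical.

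The gene lists, marker lists, comparisons, tests and alternatives were fixed before the data were examined. The 22 gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. The same test with an estimated correlation and fry were run beside it. With an estimated correlation, camera rests on the few residual degrees of freedom of 4 libraries and can hardly pass. A failure there therefore does not decide whether a list changed, nor does it make the calls with the preset correlation safer. The list called progenitor genes of the study was recalled from the study and chosen there on these samples, so it is not independent evidence. Genes named in the text were chosen by rule. Tbx2 and Tbx3 are always given. The others are the genes with the largest fold changes in each direction, 10 for the otic class, 8 for the neuron lineage and 5 elsewhere, among those with passing adjusted p, a mean of at least 20 CPM and groups that did not overlap. Mitochondrial, ribosomal protein, haemoglobin, sex-linked and predicted genes were left out. From each list, up to 4 members with the smallest p are named. Some genes that these rules chose are not reported here.

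Otic and neuron lineage cells were clustered again without Tbx2, Tbx3 and the 6192 genes changed in the otic class, so that cluster sizes did not rest on the genes being compared. Clusters were numbered, not named, and marker lists for otic subclasses were not used. After the data had been seen, a further fit used only the clusters holding cells of both genotypes. Another asked for change beyond that of 4 reference classes in which neither Tbx2 nor Tbx3 was called changed. These were leukocyte, mesenchyme, neural tube neuron and neural tube progenitor. Both genes were tested in mesenchyme only and were too low in the others. That fit kept only genes with a mean CPM in the reference classes of at least 50% of that in the class tested. Genes enriched beyond that in the class were not assessed. It used 20 sums from the same 4 libraries, so most of its residual degrees of freedom came from the reference classes. Its p-values still rest on 2 libraries per group. Near-identical gene copies were sought with spaced 60-base words (23 in Ubb) from the last 500 bases of the longest coding transcript. Exact matches in the transcripts of other genes were counted, with 10% shared as the limit.

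Alternatives were DESeq2 1.42.0 with its size factors, RLE factors, no gene filter, the replicate number as a block, leaving out each library in turn, doublets kept, no cell filter, a stricter one (2000 genes, 5% mitochondrial), counts thinned to the lowest total, equal cells per library, classes taken from the nearest control cells, and other resolutions. The last assignment gave the same class to 6664 of 6933 cKO cells (96.1%).

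Each procedure was tested on simulated data, drawn from the libraries' own means and sizes except for the share test. In the otic class (15141 genes, 199 changed), 47.8% of genes changed by a log2 fold of 0.5 were recovered, 86.8% at 1 and 92.2% at 2, and 2.60% of calls were false. In the neuron lineage these shares were 19.0%, 73.5% and 95.7%, with 5.19% false. In all kept cells they were 34.0%, 68.4% and 89.9%, with 3.65% false. At the smallest fold, recovery was 34.4% in the epibranchial class, 18.9% in mesenchyme, 17.5% in ectoderm, 13.0% in leukocytes, 7.14% in neural tube progenitors and 5.56% in neural tube neurons. At a log2 fold of 1, it was 68.1%, 81.7%, 69.9%, 64.2%, 51.6% and 62.0% in the same order, and at 2 it was 98.5%, 95.8%, 96.8%, 88.9%, 89.0% and 94.2%. False calls made up 4.26%, 4.90%, 3.2%, 0.870%, 4.67% and 0%. In the simulation of otic gene lists, 1 planted list was found and 0 of 40 unchanged lists were called by camera. Genes were simulated independently, so this could not show false calls that arise from correlated members. In the data the estimated correlation reached 0.90 for the otic G2 and M list. The interaction test recovered 67% of 100 planted differences with 5 false calls among 12585 genes. The share test recovered 96% of planted shifts over 100 simulations with 7 false calls of 900. Its shares, totals and spread were set and not taken from the libraries. The planted fall was larger than any change of a class share seen here, so this recovery does not hold for the observed shares.

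Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.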

Results

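The data comprised single-cell transcriptomes of Pax2-Cre lineage cells from the otic region of mouse embryos at E10.5, in 2 control libraries and 2 libraries from embryos with floxed Tbx2 and Tbx3 (cKO). The series title places the question in how these T-box transcription factors regulate cell fate in the otic vesicle. The control 1 library held 128205192 UMIs, control 2 held 111724972, cKO 1 held 106769747 and cKO 2 held 124986694. Kept cells had median UMI counts of 28498, 26970, 29784.5 and 30081.0 in that order, and median numbers of detected genes of 5316, 5157, 5190.0 and 5215. The median mitochondrial share of kept cells was 2.41% and 2.96% in the control libraries and 1.31% and 1.38% in the cKO libraries.

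Otic epithelium-like cells made up 55.3% and 50.8% of the control libraries and 34.3% and 53.9% of the cKO libraries. Placodal sensory neuron-like cells, the lineage of the cochleovestibular ganglion, made up 18.2% ± 2.43 (SD, n = 2) of control and 9.98% ± 0.322 of cKO cells. Their log2 ratio was -0.87 (adjusted p = 0.533). Surface or pharyngeal ectoderm-like cells were 3.46% ± 2.97 of control and 9.12% ± 1.81 of cKO cells (adjusted p = 0.533). Epibranchial visceral sensory neuron-like cells were 7.65% ± 0.148 and 8.18% ± 1.77 (adjusted p = 0.816). None of these differences passed: by edgeR, 0 of 10 class shares changed, and 0 had an unadjusted p under 0.05 (the smallest came from the neuron lineage). The question of cell composition is limited by dissection and sorting, which can set these shares. Unnamed cells were 4.63% and 2.67% of the control libraries and 13.2% and 9.10% of the cKO libraries.

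**Figure D1:**
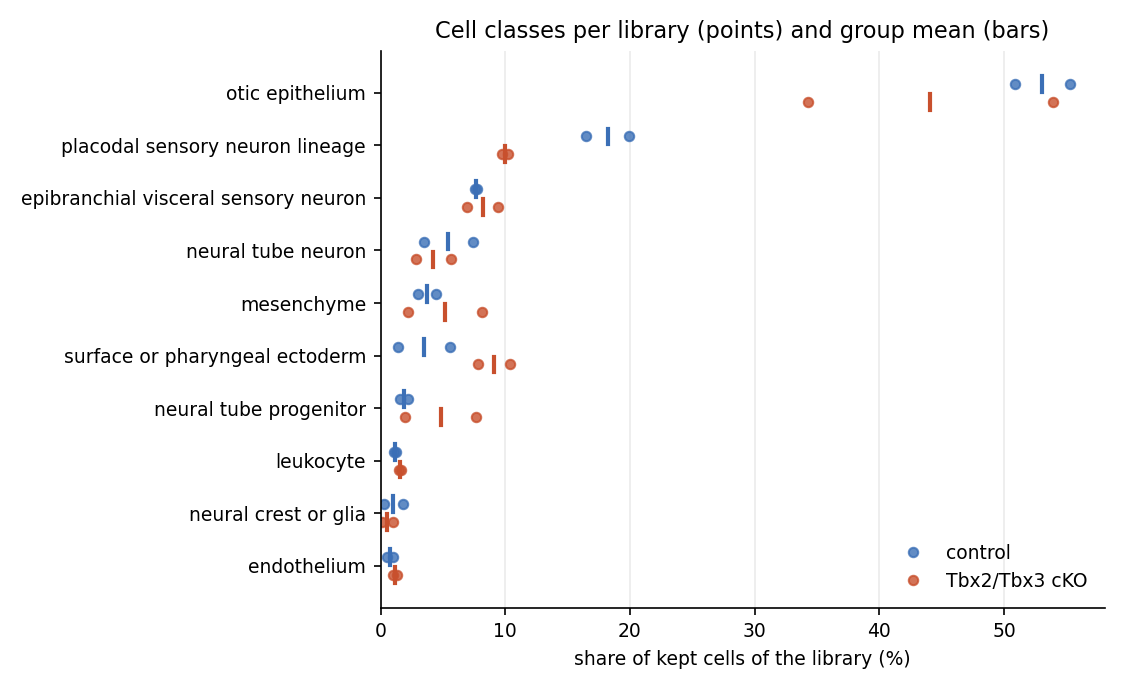
Percent of kept cells in each named class, with a point for each of the 4 libraries and a bar for each group mean. Otic epithelium-like cells range from 34.3% in cKO 1 to 55.3% in control 1, and none of the 10 class shares passed the test.

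The clusters behind the main classes differed by genotype. In the otic class, clusters 2 and 3 held 65.4% of cKO cells and 0.227% of control cells, while clusters 9, 10, 11, 13, 14, 20 and 27 held 78.1% of control cells and 3.25% of cKO cells. Clusters 4, 6 and 22 were shared, with 21.7% of control and 31.3% of cKO otic cells. In the neuron lineage, clusters 17 and 21 held 43.5% of control and 6.06% of cKO cells, and the shared clusters 1 and 19 held 56.5% and 93.9%. In the epibranchial class, cluster 8 held 40.1% of control and 64.9% of cKO cells, and cluster 12 held 59.9% and 35.1%. These clusters were formed on all variable genes, including those that differ by genotype.

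The targeted genes came first. Tbx3 (ENSMUSG00000018604, mm10 chromosome 5, 119670669 to 119684724) fell in otic cells from 58.6 ± 2.60 to 21.4 ± 3.79 CPM, a log2 change of -1.46 (SE 0.11, adjusted p = 4.52e-05). The control 1 and 2 libraries had 60.4 and 56.7 CPM, and the cKO 1 and 2 libraries 24.1 and 18.7. Composition enters this fall. In control, clusters 10 (149 and 129 CPM), 11 (136 and 139) and 27 (107 and 103) were high in Tbx3. These clusters held few cKO cells. In the shared cluster 4 Tbx3 stood at 6.67 and 12.4 CPM in control and 8.05 and 6.56 in cKO. In cluster 6 it stood at 4.99 and 4.72 against 3.93 and 5.899. In cluster 22 it stood at 24.6 and 16.98 against 3.77 and 2.59, so it fell there. Tbx2 (ENSMUSG00000000093, chromosome 11, 85832551 to 85841948) fell in otic cells from 92.1 ± 4.51 to 72.6 ± 1.99 CPM, with 88.9 and 95.3 in the control and 74.0 and 71.2 in the cKO libraries (log2 -0.34, SE 0.07, adjusted p = 0.00517). In the neuron lineage Tbx3 fell from 98.1 ± 1.68 to 31.2 ± 5.18 CPM (log2 -1.66, SE 0.12, adjusted p = 1.27e-04), and Tbx2 stood at 18.7 ± 0.838 and 22.4 ± 2.11 CPM (adjusted p = 0.126). In the shared cluster 19 Tbx2 stood at 59.6 and 78.2 CPM in control and 32.1 and 35.3 in cKO. In cluster 1 it stood at 18.8 and 26.4 against 16.8 and 19.6. Cluster 19 was 9.08% of control and 27.4% of cKO cells of the class, so composition enters the class value. Leukocyte-like cells, a check for free RNA, held 1, 3, 0 and 1 Tbx2 UMIs in the control 1, control 2, cKO 1 and cKO 2 libraries, at most 1.87 CPM per total UMI, and 0, 1, 0 and 0 Tbx3 UMIs. The labels do not name the deleted exons, and the counted 3′ ends may lie outside them, so transcript left in cKO cells says little about the deletion.

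Over all kept cells, Tbx3 fell from 52.5 ± 1.38 to 17.2 ± 0.116 CPM (log2 -1.61, SE 0.06, adjusted p = 0.00148), with 53.5 and 51.6 in the control and 17.3 and 17.1 in the cKO libraries. Tbx2 fell from 57.9 ± 1.01 to 41.8 ± 8.16 CPM (log2 -0.47, SE 0.13, adjusted p = 0.0479), with 57.2 and 58.7 in the control and 36.005 and 47.5 in the cKO libraries. The Tbx2 call did not pass with RLE factors (adjusted p = 0.0548), nor without the control 1 (0.114), control 2 (0.162) or cKO 1 (0.0675) library. In the epibranchial class Tbx2 fell (log2 -1.17, SE 0.30, adjusted p = 0.0271) and Tbx3 had a log2 change of 0.20 (adjusted p = 0.626); with either control library left out, 0 (control 1) and 3 (control 2) genes passed in that class by edgeR. In ectoderm-like cells Tbx3 fell from 4.07 ± 1.87 to 1.33 ± 0.260 CPM (log2 -1.85, adjusted p = 0.0449). In mesenchyme-like cells Tbx3 (0.32, adjusted p = 0.775) and Tbx2 (-0.16, adjusted p = 0.814) did not pass.

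The otic comparison asked which genes depend on Tbx2 and Tbx3 in the vesicle epithelium. Oc90 (ENSMUSG00000015001, chromosome 15, 65876053 to 65912397), the main protein of otoconia, fell from 404 ± 110 to 32.7 ± 8.46 CPM (log2 -3.63, SE 0.22, n = 2 libraries per group). Otol1, which encodes the otolith scaffold protein otolin, fell by 2.05 on the log2 scale (SE 0.18). Cxcl12 (ENSMUSG00000061353, chromosome 6, 117168535 to 117181367), a chemokine, rose from 9.59 ± 0.00544 to 85.2 ± 18.1 CPM (log2 3.15, SE 0.14). Sfrp2 (ENSMUSG00000027996, chromosome 3, 83766321 to 83774316), a secreted WNT modulator, rose from 17.6 ± 1.79 to 131 ± 14.6 CPM (log2 2.89, SE 0.10).

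By edgeR, 6192 of 15356 tested genes changed in otic cells (40.3%), 3213 up and 2979 down, of which 367 rose and 811 fell by more than 2-fold. The other named genes that rose were Ubb, a ubiquitin gene (log2 3.18, SE 0.09; 227 ± 28.0 to 2059.9 ± 64.0 CPM), the metallothionein Mt1 (2.75, SE 0.09), the collagen-processing enhancer Pcolce2 (2.42, SE 0.09), the heparan sulfate sulfotransferase Hs3st1 (1.64, SE 0.11), the homeobox gene Prrx2 (1.54, SE 0.15), the retinoic acid-binding Crabp1 (1.48, SE 0.08), Armc10 (1.40, SE 0.21) and Schip1 (1.38, SE 0.08). Those that fell included the growth factor Tgfb2 (-2.77, SE 0.15; 41.5 ± 3.45 to 5.96 ± 1.57 CPM), the integrin subunit Itga4 (-2.36, SE 0.16), the zinc finger factor Zbtb20 (-2.16, SE 0.08), C1qtnf12 (-2.12, SE 0.14), the glucocorticoid-inactivating enzyme Hsd11b2 (-2.11, SE 0.12) and Cnmd, chondromodulin (-2.04, SE 0.16). Adjusted p ranged from 1.59e-06 (Mt1) to 0.00133 (Armc10) over these genes. The median mitochondrial share of otic cells was 2.29% and 2.87% in the control and 1.20% and 1.27% in the cKO libraries. The otic sums held 71590206 and 56950927 UMIs in the control and 42834832 and 71235158 in the cKO libraries.

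**Figure D2:**
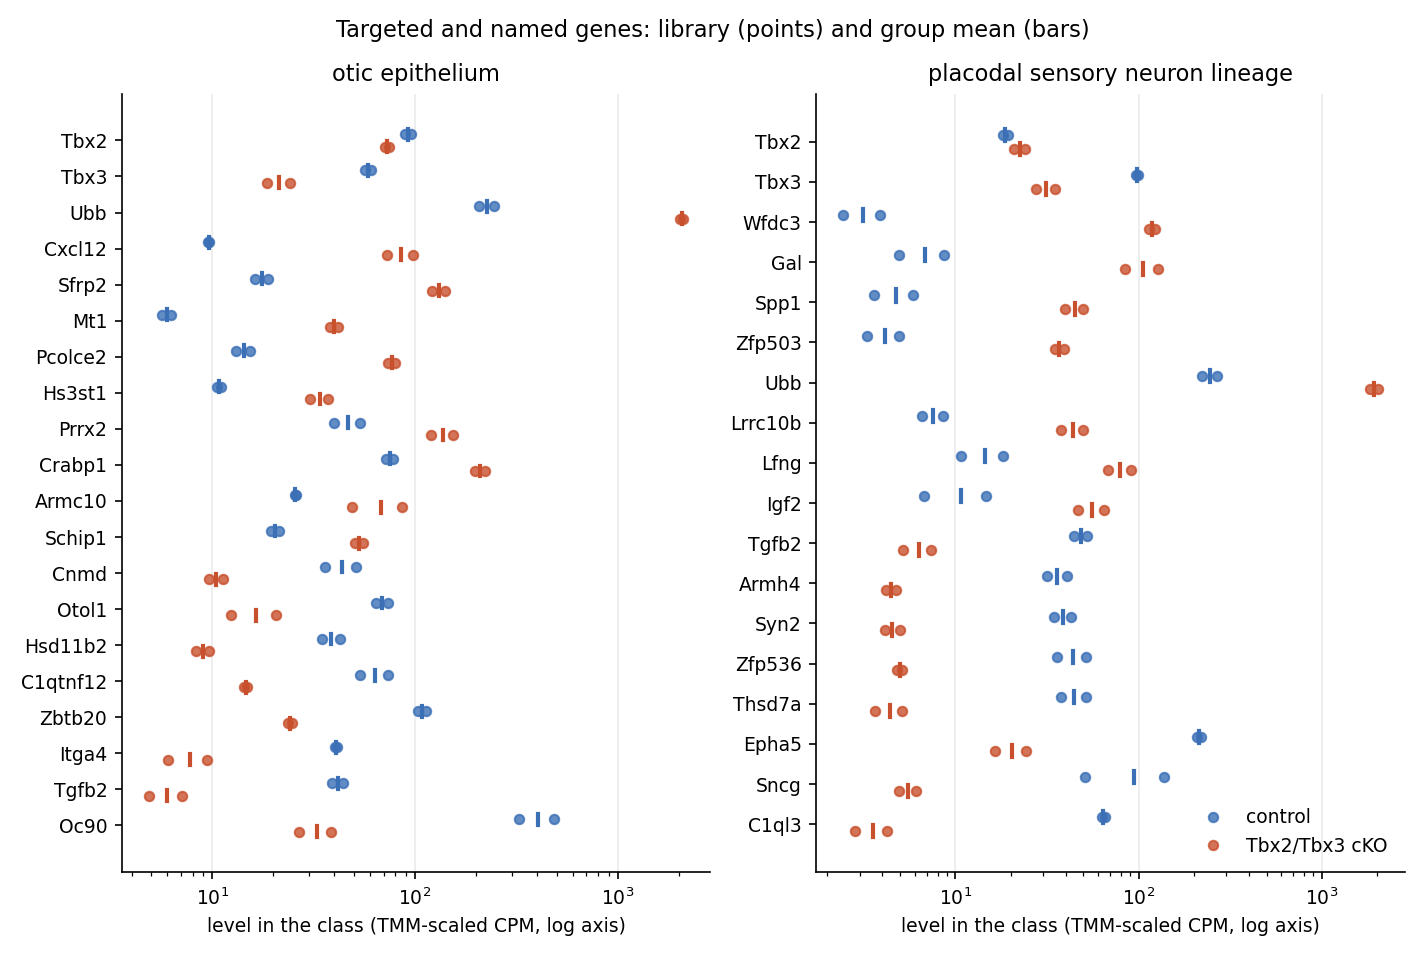
Levels in CPM (log axis) of the targeted and named genes in the otic and neuron lineage classes, with a point for each of the 4 libraries and a bar for each group mean. In otic cells Cxcl12 stands at 9.59 CPM in control and 85.2 in cKO, and Oc90 at 404 and 32.7.

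Among the otic identity lists, nonsensory and otolith genes fell: 9 of 11 measured members fell, 1 rose and 1 did not pass, with a median log2 change of -2.05 (camera adjusted p = 0.0016, and adjusted p = 0.403 with an estimated correlation). Its strongest members were the homeobox genes Otx2 (ENSMUSG00000021848, chromosome 14, 48657677 to 48673819; -4.03) and Otx1 (ENSMUSG00000005917, chromosome 11, 21994764 to 22002897; -3.84, 29.4 ± 0.680 to 2.12 ± 0.490 CPM) and Gata2 (-2.67), beside Oc90. Dorsal otic patterning genes fell in 10 of 11 cases, with a median of -0.46 (adjusted p = 0.00259, and adjusted p = 0.403 with an estimated correlation), among them Msx2 (-0.85), Hmx2 (-0.73), Hmx3 (-0.53) and Dlx6 (-0.46). Ventral otic patterning genes fell in 6 and rose in 2 of 10 cases (median -1.11, adjusted p = 0.0363, and adjusted p = 0.406 with an estimated correlation), with Ptch1 at -1.09 and Gata3 at -1.26 beside Otx1 and Otx2. The ventral call did not pass without control 1 (0.0513) or control 2 (0.0581). Adjusted over the list alone, the counts of members that rose and fell were the same in these 3 lists. The otic epithelium marker list also fell, with 9 members down and 1 up of 12 (camera adjusted p = 0.0274, and adjusted p = 0.745 with an estimated correlation). Over that list alone, 9 were down and 2 up.

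Progenitor genes of the study rose in 4 of 6 cases, with a median of 1.16 (camera adjusted p = 0.0195, and adjusted p = 0.406 with an estimated correlation). They included Sox3 (3.06; 1.28 ± 0.00605 to 10.8 ± 1.49 CPM), Cxcl12, Fgf18 (1.48) and Pou3f3 (0.84). This list was chosen by the study on these samples, so its count, 4 also when adjusted over the list alone, is not independent evidence. In the wider list of otic placode and progenitor genes 5 of 16 rose, 2 fell and 9 did not pass (adjusted p = 0.343); adjusted over the list alone, 6 rose and 2 fell. Sox3 and the FGF antagonist Spry1 (0.93) rose, while Gata3 and Sox9 (-0.90) fell. Of 14 prosensory genes, 4 rose and 4 fell (adjusted p = 0.874), also when adjusted over the list alone; Lfng (1.20) and Hey1 (0.74) rose, and Fgf10 (-1.13) and Isl1 (-0.93) fell. The median of this list was 0.02 and its mean -0.03.

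Neuroblast specification genes rose in otic cells, with 10 of 16 up and 3 down (median 0.66, camera adjusted p = 0.0363), among them the Notch ligand Dll1 (1.82), Eya2 (1.75), the FGF ligand Fgf3 (1.85) and Ebf1 (1.20). Adjusted over the list alone, 10 rose and 4 fell. This call did not pass without control 2 (0.0509) or cKO 1 (0.0628), and had an adjusted p = 0.607 with an estimated correlation. Neuronal differentiation genes fell, with 10 of 20 down and 2 up (median -0.57, adjusted p = 0.0195, and adjusted p = 0.406 with an estimated correlation); adjusted over the list alone, 12 fell and 2 rose. Dcx (-2.84), Ntrk2 (-1.04) and Gap43 (-0.60), genes of migrating and growing neurons, fell, and the intermediate filament gene Ina rose (1.63). Notch pathway genes rose in 10 of 16 cases and fell in 3 (median 0.50, adjusted p = 0.0363, and adjusted p = 0.494 with an estimated correlation), with the same counts adjusted over the list alone. Dll1, Lfng, Hey1 and the ligand Jag1 (0.50) were among those that rose.

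Among signalling lists, BMP genes fell in 12 of 15 cases and rose in 2 (median -0.60, camera adjusted p = 0.00476, and adjusted p = 0.403 with an estimated correlation), including the inhibitors Smad7 (-1.09) and Bambi (-0.95) and Msx2, while the BMP antagonist Nog rose (2.14). Hedgehog genes fell in 7 of 10 cases with 0 up (median -0.60, adjusted p = 0.0013, and adjusted p = 0.403 with an estimated correlation), among them the target and inhibitor genes Hhip (-3.58), Gli1 (-1.68) and Ptch1 (-1.09) and the co-receptor Cdon (-1.72); 8 fell when adjusted over the list alone. FGF genes rose in 7 and fell in 6 of 19 cases (adjusted p = 0.343), with Fgf8 (2.20), Fgf3 and Spry1 up. WNT genes rose in 5 and fell in 6 of 19 cases (adjusted p = 0.839), with Sfrp2 and the target Sp5 (1.23) up and Rspo3 (-1.44) and Sfrp1 (-0.84) down. Retinoic acid genes rose in 4 and fell in 4 of 14 cases (adjusted p = 0.934; 4 and 5 over the list alone). The synthesis gene Aldh1a2 fell from 10.1 to 0.166 CPM (-5.98) and the degrading Cyp26c1 fell (-2.54), while Crabp1 rose. The retinoic acid list had a median of -0.05 and a mean of -0.58, and its test pointed up. In the T-box list 3 genes were measured (adjusted p = 0.82). Tbx1, another otic T-box factor, fell from 84.1 CPM in control (log2 -1.27), Tbx18 rose from 1 to 19 counts in all, and Tbx6 stood at 1.16 (adjusted p = 0.147; 0.0481 without cKO 1).

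Cell cycle S phase genes rose in 12 of 18 cases with 0 down (median 0.30, camera adjusted p = 0.00137, and adjusted p = 0.607 with an estimated correlation), among them Rrm2 (0.85), Chaf1b (0.72), Gins2 (0.57) and Tyms (0.54). G2 and M phase genes rose in 8 and fell in 2 of 18 cases (adjusted p = 0.262; 0.0140 without control 1), with Ccnb2 (0.50) and Bub1 (0.46) up and Mki67 (-0.57) down. Glycolysis and hypoxia genes rose in 5 of 13 cases with 0 down (median 0.38, adjusted p = 0.0429, and adjusted p = 0.914 with an estimated correlation), with Vegfa (1.21) and the glucose transporter Slc2a1 (0.56) up. That call did not pass without control 1 (0.0538), control 2 (0.116) or cKO 1 (0.666). Beyond the reference classes used later the direction turned and the list was lower in otic cells, with 5 of 13 members down and 1 up (median -0.42, adjusted p = 3.89e-07; 8 down and 1 up over the list alone). Of 5 cyclin-dependent kinase inhibitors 0 passed by edgeR; the list had a median of 0.15, a mean of -0.01 and an adjusted p of 0.934. Cdkn1a stood at 0.30 and passed without cKO 1 (adjusted p = 1.64e-06), and Cdkn1c stood at -0.13 and passed without control 1 (0.0494). Of 14 p53 targets 3 rose and 3 fell (adjusted p = 0.985; 3 and 5 over the list alone), with the apoptosis genes Bbc3 (0.50) and Bax (0.46) up and Zmat3 (-0.43) down; the median was -0.05, the mean -0.03 and the test pointed up. Of 13 epithelial junction genes 2 rose and 4 fell (adjusted p = 0.839; 3 and 5 over the list alone), with Cldn7 (0.33) up and Krt8 (-0.39) down; the median was 0.00 and the mean -0.06. Of 15 dissociation stress genes 3 rose and 3 fell (adjusted p = 0.82), with Ier2 (0.43) and Hsp90aa1 (0.36) up and Nr4a1 (-0.89) down. Counts over the list alone are given where they differ from those over all genes.

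**Figure D3:**
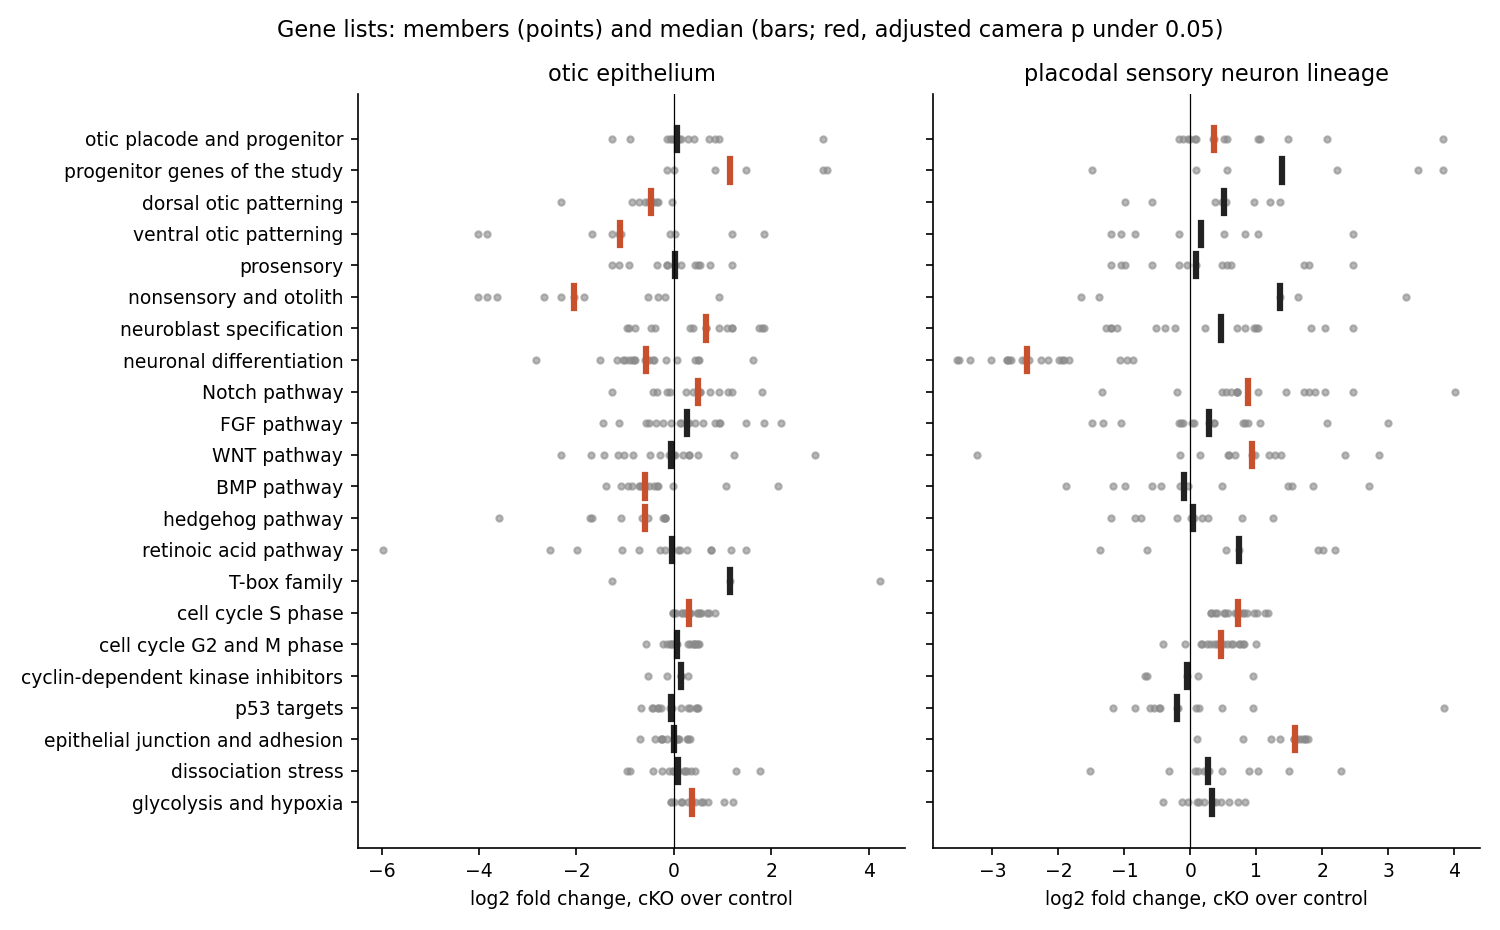
Log2 fold changes (cKO over control) of the measured members of each gene list in the otic and neuron lineage classes, with a point for each gene and the list median as a bar, red where the camera test passed. The nonsensory and otolith median is -2.05 in otic cells, and the neuronal differentiation median is -2.48 in the neuron lineage.

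In the otic class 11 of the 22 lists passed, 5 up and 6 down. With an estimated correlation 0 passed by camera, and 0 had an unadjusted p under 0.05. That test has few residual degrees of freedom here, so this does not decide. The hedgehog list had an estimated correlation of -0.093, below the preset one. Even so, its unadjusted camera p went from 5.90e-05 to 0.0524. Estimates for the passing lists ranged from -0.200 (progenitor genes of the study) to 0.837 (glycolysis), with S phase at 0.389. Where the estimate lies far above the preset one, the preset correlation can make p too small. Of the 11 lists, 7 also passed by fry, which asks whether a list moves on balance and not whether it differs from other genes. Of the marker lists for other cells, the neural crest or glia list fell, with 6 of 7 members down (adjusted p = 0.00251, and adjusted p = 0.745 with an estimated correlation), among them Ednrb (-2.70), Erbb3 (-0.95) and Moxd1 (-0.88). The other 10 lists measured there did not pass, with adjusted p from 0.263 to 0.838: placodal sensory neuron, epibranchial neuron, neural tube progenitor, neural tube neuron, ectoderm, pharyngeal endoderm, mesenchyme, endothelium, leukocyte and melanoblast. Erythroid and muscle progenitor markers were too low to be tested in otic cells.

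Within the shared otic clusters 4, 6 and 22, pooled, a choice made after the data had been seen, 4341 of 13167 genes changed, 2359 up and 1982 down, and 3482 of these had passed in the same direction in the whole class. The named otic genes given above passed there, with Oc90 at -2.74, Otol1 at -0.75, Sfrp2 at 3.34 and Cxcl12 at 1.94; Hsd11b2 (-0.08, adjusted p = 0.737) and Cnmd (0.04, adjusted p = 0.812) were the exceptions. Tbx2 fell there (-0.53, adjusted p = 0.00195), and Tbx3 stood at -0.39 (adjusted p = 0.0847). By camera with the preset correlation, the nonsensory list fell there (adjusted p = 0.0361). The progenitor genes of the study (0.0061), prosensory (9.31e-04), neuroblast (0.0226), Notch (0.00164) and G2 and M (9.31e-04) lists rose by the same test. The dorsal (0.0676), ventral (0.391), neuronal differentiation (0.292), BMP (0.852), hedgehog (0.391), S phase (0.618) and glycolysis (0.108) lists did not pass. The mix of these clusters differed, with cluster 4 at 7.56% of control and 19.4% of cKO otic cells, cluster 6 at 9.35% and 8.60% and cluster 22 at 4.79% and 3.29%, so composition still enters this fit.

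Many otic changes were also seen in the 4 reference classes (mesenchyme, leukocyte, neural tube neuron and neural tube progenitor), in which a change of the targeted genes was not detected in mesenchyme and could not be tested in the other 3, where both genes were too low. Across 6911 genes, otic log2 fold changes correlated at r = 0.731 with the median of the 4 reference classes. Among those of them called changed in otic cells, 91.1% had the same sign. Genes are not independent replicates. The same libraries enter both sides, and differences between libraries of one genotype also correlated, at 0.481 for control and 0.631 for cKO, so a value of 0 is not to be expected without a genotype effect. By the fit that asks for change beyond the reference classes, chosen after the data had been seen, 447 of 11576 otic genes passed (185 up, 262 down), among them 386 of the 4987 otic calls assessed (7.74%). Another 1205 otic calls were not assessed, as that fit kept only genes with a mean reference level of at least 50% of the otic level. Cxcl12 (3.03), Sfrp2 (3.03), Mt1 (2.27), Prrx2 (1.77), Crabp1 (0.96), Itga4 (-2.38), Zbtb20 (-1.43) and Hsd11b2 (-1.37) passed this test, and Ubb (0.16, adjusted p = 0.497) and Armc10 (0.41, adjusted p = 0.369) did not. Oc90, Otol1 and the other named otic genes were not assessed. Of the gene lists, Notch (0.0133) and S phase (5.90e-05) passed upward by camera, though only 2 of 12 and 1 of 17 single members passed (2 and 5 over the list alone), and glycolysis turned down as given above. The neuroblast (0.0713), neuronal differentiation (0.718), BMP (0.491), hedgehog (0.147) and ventral (0.524) lists and the progenitor genes of the study (0.0775) did not pass there, and the nonsensory and dorsal lists were not assessed. An estimated correlation was not used in that fit, and its residual spread comes mostly from the reference classes.

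The neuron lineage comparison asked the same of the cochleovestibular ganglion and its precursors. Genes of neuronal maturation fell together: all 20 measured neuronal differentiation genes fell, with a median log2 change of -2.48 (camera adjusted p = 9.11e-11, and adjusted p = 0.690 with an estimated correlation). Neurog1 (ENSMUSG00000048904, chromosome 13, 56250478 to 56252163), the factor that specifies these neuroblasts, rose from 57.9 ± 1.73 to 206 ± 7.69 CPM (log2 1.83, adjusted p = 4.59e-05, n = 2 libraries per group). The synaptic organizer C1ql3 (ENSMUSG00000049630, chromosome 2, 13003457 to 13011806) fell from 64.3 ± 1.64 to 3.53 ± 0.988 CPM (-4.17, SE 0.16), and Wfdc3 (ENSMUSG00000076434, chromosome 2, 164731180 to 164745931), a WAP-domain gene, rose from 3.15 ± 1.00 to 118 ± 6.03 CPM (5.24, SE 0.17).

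By edgeR, 4922 of 12970 tested genes changed in the neuron lineage (37.9%), 2431 up and 2491 down, of which 529 rose and 1054 fell by more than 2-fold. Without cKO 1 the count was 3170, and without cKO 2 it was 3053. The other named genes that rose were the neuropeptide gene Gal (3.97, SE 0.28; 6.82 ± 2.67 to 106 ± 31.2 CPM), Spp1, osteopontin (3.26, SE 0.21), the zinc finger gene Zfp503 (3.15, SE 0.18), Ubb (2.98, SE 0.11), Lrrc10b (2.53, SE 0.18), Lfng, a glycosyltransferase acting on Notch (2.47, SE 0.23), and the growth factor Igf2 (2.39, SE 0.30). Those that fell were the synuclein gene Sncg (-4.09, SE 0.48; 94.3 ± 61.2 to 5.52 ± 0.824 CPM), the ephrin receptor Epha5 (-3.38, SE 0.16; 214 ± 6.66 to 20.5 ± 5.56 CPM), Thsd7a (-3.34), Zfp536 (-3.15), the synapsin Syn2 (-3.08), Armh4 (-3.01) and Tgfb2 (-2.93). Adjusted p ranged from 1.79e-05 (Ubb) to 0.00122 (Igf2) over the 16 genes. The median mitochondrial share of these cells was 2.41% and 2.96% in the control and 1.30% and 1.37% in the cKO libraries. Their sums held 17309487 and 19420992 UMIs in the control and 11480740 and 12727473 in the cKO libraries.

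With an estimated correlation the adjusted p was 0.690 for neuronal differentiation and for each of the next 5 lists. The neuronal differentiation members Ntrk2 (-3.51), Ntrk3 (-2.74), Gap43 (-2.51; 460 to 80.8 CPM) and Stmn3 (-2.16) encode neurotrophin receptors and proteins of axon growth. Cell cycle S phase genes rose in 18 of 18 cases (median 0.72, adjusted p = 1.85e-06), with Rrm2 (1.13), Chaf1b (1.02), Gins2 (0.86) and Slbp (0.74). Epithelial junction genes rose in 11 of 12 cases with 0 down (median 1.58, adjusted p = 1.43e-05), among them Krt18 (1.74), Cldn7 (1.74), Epcam (1.56) and Cldn6 (1.23). Notch pathway genes rose in 12 of 16 cases and fell in 1 (median 0.87, adjusted p = 8.49e-05), with the target genes Hes5 (4.01), Heyl (1.89) and Hey1 (1.80) and with Lfng. WNT pathway genes rose in 8 of 13 cases and fell in 1 (median 0.94, adjusted p = 0.00213), with Sp5 (2.86), Sfrp2 (1.37) and Nkd1 (0.94). Otic placode and progenitor genes rose in 7 of 15 cases with 0 down (median 0.36, adjusted p = 0.0112), with Sox3 (3.82), Etv4 (2.07), Pax8 (1.48) and Spry1 (1.05). G2 and M phase genes rose in 12 of 18 cases and fell in 1 (median 0.46, adjusted p = 0.00119, and adjusted p = 0.826 with an estimated correlation), with Plk1 (0.99), Ccnb2 (0.81), Ube2c (0.79) and Cdk1 (0.75). Counts adjusted over the list alone were the same as over all genes for these lists.

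Of the other neuron lineage lists, neuroblast specification genes rose in 8 and fell in 5 of 16 cases (adjusted p = 0.259; 9 and 6 over the list alone), with Neurog1 and Hes6 (0.99) up and Nhlh1 (-1.28) down. Progenitor genes of the study rose in 4 and fell in 1 of 6 cases (adjusted p = 0.0835), with Cxcl12 (3.45) and Pou3f3 (2.22) up and Fgf18 (-1.49) down; the list passed without control 1 (0.0316), control 2 (0.0385) or cKO 1 (0.0465), and was chosen by the study on these samples. Nonsensory and otolith genes rose in 3 and fell in 2 of 5 cases (0.714), prosensory genes in 5 and 3 of 13 (0.726), ventral genes in 4 and 2 of 8 (0.869), and dorsal genes rose in 2 of 8 with 0 down (0.259; 0.0274 without control 1). BMP genes rose in 4 and fell in 1 of 12 cases (0.869; 4 and 3 over the list alone), with Nog (2.70) and Id1 (1.86) up and Id4 (-1.88) down; the median was -0.09, the mean 0.23 and the test pointed up. FGF genes rose in 6 and fell in 3 of 17 (0.243; 0.0370 without control 1). Retinoic acid genes rose in 4 and fell in 1 of 7 (0.165; 0.0429 without control 1 and 0.0293 without cKO 1; 5 and 1 over the list alone), with Crabp2 (1.93) up. Among 10 hedgehog genes (0.869; 0 up and 1 down over the list alone) Ptch1 fell (-0.84) and Boc rose (0.79), a call lost without control 2 (0.146), cKO 1 (0.140) or cKO 2 (0.113); the median was 0.03, the mean -0.05 and the test pointed up. Among 5 kinase inhibitors (0.869) Cdkn1a rose (0.94) and Cdkn2d fell (-0.66). Of 13 p53 targets 3 rose and 4 fell (0.809; 3 and 6 over the list alone), with a median of -0.21, a mean of 0.07 and a test that pointed down. Stress genes rose in 3 and fell in 1 of 12 (0.185; 0.0419 without cKO 2), and glycolysis genes rose in 2 of 13 with 0 down (0.187; 4.19e-04 without cKO 2; 1 and 0 over the list alone). Values in parentheses after a list are camera adjusted p, and T-box genes were too few to be tested as a list here.

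In the neuron lineage 7 of 21 lists passed, 6 up and 1 down. With an estimated correlation 0 passed by camera, with 1 at an unadjusted p under 0.05, and 0 passed by fry. The estimates were 0.694 for neuronal differentiation, 0.764 for S phase, 0.899 for G2 and M, 0.579 for WNT and 0.573 for epithelial genes. They were 0.157 for the placode list and -0.001 for Notch, against a preset 0.01. The preset correlation can thus make p too small for the lists with high estimates. The placodal sensory neuron marker list fell, with 9 of 12 members down and 1 up (camera adjusted p = 0.00951). Over that list alone, 9 were down and 2 up. All 3 measured surface ectoderm markers rose (camera adjusted p = 0.00951). Both lists had an adjusted p = 0.560 with an estimated correlation. The other 5 marker lists measured there (otic epithelium, epibranchial neuron, neural tube progenitor, neural tube neuron, and neural crest or glia) had adjusted p from 0.237 to 0.397. Within the shared clusters 1 and 19, pooled, 4051 of 12356 genes changed, and all 16 named genes passed, with Wfdc3 at 4.66, C1ql3 at -3.57, Sncg at -2.28 and Epha5 at -1.50. Of the lists there, by camera with the preset correlation, neuronal differentiation fell (16 of 19 members, median -1.23, adjusted p = 3.01e-06). The Notch (8.31e-05), WNT (0.0451), S phase (0.0463) and epithelial (7.61e-05) lists rose, while the placode (0.133) and G2 and M (0.584) lists did not pass. The mix of these clusters differed, with cluster 1 at 47.4% of control and 66.5% of cKO cells of the class and cluster 19 at 9.08% and 27.4%, so composition still enters this fit.

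Neuron lineage log2 fold changes correlated at r = 0.616 across 6928 genes with the median of the reference classes, again with the same libraries on both sides. Among those of them called changed in the neuron lineage, 88.9% had the same sign. Beyond the reference classes 1356 of 11213 genes passed (577 up, 779 down), among them 1170 of the 4139 neuron lineage calls assessed (28.3%); 783 calls were not assessed. Zfp503 (3.26), Igf2 (1.71), C1ql3 (-4.38), Sncg (-3.73), Thsd7a (-3.04), Zfp536 (-2.66) and Armh4 (-2.60) passed this test, and Ubb (0.01, adjusted p = 0.969) did not. Of the gene lists, neuronal differentiation still fell (16 of 16 assessed members, adjusted p = 1.53e-10), and the S phase (17 of 18 members, 5.50e-14; 18 over the list alone), G2 and M (12 of 18, 1.06e-05; 15 over the list alone) and Notch (5 of 11, 9.57e-04; 8 up and 1 down over the list alone) lists rose. The WNT (0.0751) and placode (0.131) lists did not pass, and the epithelial list was not assessed. These p-values draw their residual spread mostly from the reference classes and rest on 2 libraries per group. Retinoic acid genes rose (3 of 6, 0.00213; 4 over the list alone) and p53 targets fell (3 of 10, 0.0195) beyond the reference classes, and glycolysis genes were lower, with 5 of 13 down and 0 up (7.44e-05; 6 down over the list alone).

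The responses of both classes were then compared directly. The genotype effect differed between otic and neuron lineage cells for 2463 of 15150 genes, with 1297 more positive and 1166 more negative in otic cells. The balance turned with RLE factors (1206 and 1293) and with no gene filter (1538 and 1611). The count was 1599 without cKO 1 (785 and 814) and 1482 without cKO 2 (730 and 752). Sfrp2 rose more in otic cells (difference 1.51 on the log2 scale) and Oc90 fell more there (-1.98). For C1ql3 (4.85) and Epha5 (2.49), which fell in the neuron lineage, the effect was more positive in otic cells. For Gal (-4.36) and Wfdc3 (-2.75), which rose in the neuron lineage, it was more negative in otic cells. The Tbx2 effect differed as well (-0.61). Composition enters its neuron lineage value, since Tbx2 was lower in cKO in the shared cluster 19, which grew from 9.08% to 27.4% of the class.

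When otic and neuron lineage cells, 9122 in all, were clustered without the genes called changed in the otic class, the shares of 10 of 19 clusters differed by edgeR, 3 higher and 7 lower in cKO. Clusters led by Otx1 and Otx2, genes of the ventral vesicle wall, were nearly empty in cKO. Cluster 7, led by Rorb, Gsc and Otx1, went from 9.43% ± 2.60 to 0.0773% ± 0.00955 of these cells (adjusted p = 1.54e-10). Cluster 15, led by Otx2, Otx1 and Vmo1, went from 4.90% ± 0.0965 to 0.0630% ± 0.0891 (adjusted p = 6.39e-09), with 0 cells in cKO 1, which allows a share of up to 0.212%. Neuronal clusters 12, with Epha5 and Ntrk2, and 13, with Hmx1, Onecut2 and Sncg, went from 5.63% ± 1.20 to 0.647% ± 0.381 and from 5.602% ± 2.58 to 0.619% ± 0.222 (adjusted p = 4.83e-06 for both). Cluster 10, led by genes such as Sfrp2, Sox3 and Cxcl12, rose from 1.70% ± 0.453 to 7.63% ± 2.52 (adjusted p = 2.36e-04). Cluster 6 rose from 2.76% ± 0.574 to 9.31% ± 2.99 (0.00162), and the histone-rich cluster 5 from 6.199% ± 0.601 to 13.6% ± 1.71 (0.0338). Leading genes of all clusters were ranked with the changed genes included, and those of cluster 10 also held Ubb. They can thus reflect genotype and do not show which cell state grew or shrank. Clusters 18 (0.00162), 17 (0.0461) and 19 (0.0338) fell, the last resting on control 2, which held 47 of its cells. The number of clusters that differed was 5 without control 2, 4 without cKO 2 and 1 with the replicate number as a block. Genes changed in the neuron lineage alone were not left out, and 762 of the 2000 genes used were of that kind, so the neuronal clusters are less protected from circularity than the otic ones. Another 251 were not tested in the otic class and may have changed there.

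**Figure D4:**
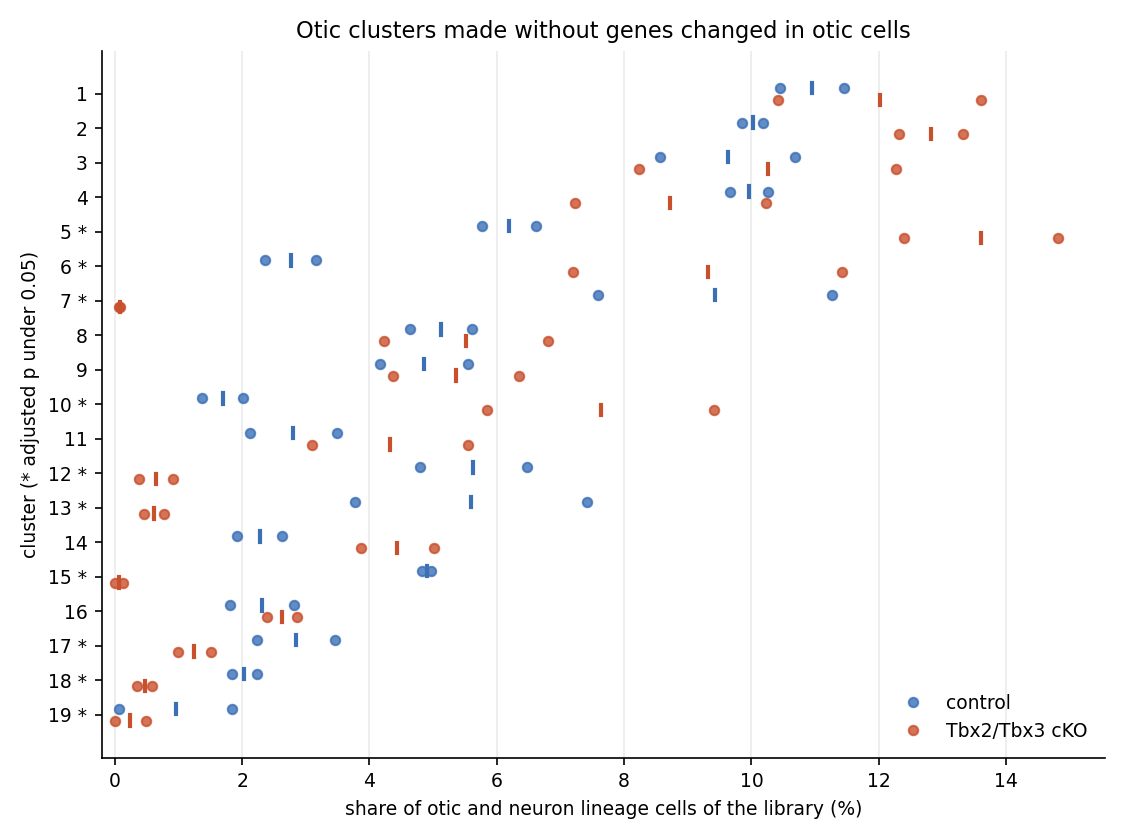
Percent of otic and neuron lineage cells in each of the 19 clusters made without the genes changed in the otic class, with a point for each of the 4 libraries, a bar for each group mean and a star where the share changed. Cluster 7 stands at 9.43% in control and 0.0773% in cKO, and cluster 10 at 1.70% and 7.63%.

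Over all kept cells, a view that mixes expression with composition, 4679 of 17321 genes changed, 2564 up and 2115 down. The named genes were mostly those of the otic class. Among them Ubb (3.09), Cxcl12 (2.31), Mt1 (2.24), Sfrp2 (2.17) and Pcolce2 (1.90) rose, and Oc90 (-3.81), the homeobox gene Hmx1 (-2.35), Tgfb2 (-2.20) and Otol1 (-2.13) fell, with adjusted p from 0.00148 to 0.0151. The count fell to 2444 without control 1, 477 without control 2, 3066 without cKO 1 and 2527 without cKO 2. Otol1 did not pass without control 2 (adjusted p = 0.0661). The total counts per library are given at the start of the text.

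In surface or pharyngeal ectoderm-like cells, 643 of 11962 genes changed, 328 up and 315 down (180 without cKO 1, 224 without cKO 2). The count was 274 with DESeq2 (167 up, 107 down), 209 with thinned counts, 48 with the 49 cells of control 2 matched in each library, 1119 with the replicate block and 1344 with no gene filter. The growth factor gene Fgf8 (ENSMUSG00000025219, chromosome 19, 45736798 to 45742915) rose from 3.25 ± 3.30 to 82.3 ± 2.84 CPM (4.13, SE 0.25, adjusted p = 1.04e-05). Rarres1 (2.38) and Cxcl12 (1.70) rose, as did the smooth muscle gene Tagln (1.70), which did not pass without control 1 (0.102), control 2 (0.0891) or cKO 1 (0.155). The axon guidance genes Robo2 (-1.85) and Sema3a (-1.39), Lratd2 (-1.42) and the neuronal RNA Bc1 (-1.37) fell. In the epibranchial class 3085 of 12793 genes changed, 1468 up and 1617 down, but 0 without control 1 and 3 without control 2 by edgeR, and 1629 by DESeq2. Fbxo2 (2.61), Gal (2.43), Krt8 (2.21) and Col13a1 (2.16) rose, and Rnf121 (-2.79), Pcp4 (-2.37), Rbms3 (63.5 to 15.6 CPM) and Syt4 (-1.92) fell. Without control 1 the adjusted p was 0.0530 for Rnf121 and 0.173 for the other 7, and without control 2 it was 0.150 for Col13a1 and 0.147 for Fbxo2, Gal, Krt8, Pcp4, Rbms3 and Syt4.

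In mesenchyme-like cells 642 of 10360 genes changed, 332 up and 310 down (1195 without control 1, 283 without cKO 1, 275 with equal cells, 1235 with no gene filter). By DESeq2 306 changed, with the balance toward higher levels, 216 up and 90 down. Sparcl1 (2.27), the lactate transporter Slc16a3 (1.96), the hypoxia-responsive Bnip3 (1.84) and Armc10 (1.55) rose, and Pcdh10 (-2.34), Epha7 (-2.30), Pou3f4 (-2.28), a factor of the periotic mesenchyme, and Tle5 (-1.85) fell. In neural tube neuron-like cells 124 of 10519 genes changed, 47 up and 77 down (70 without control 2, 248 without cKO 2, 921 with no gene filter), and by DESeq2 78 rose and 71 fell. The granin Scg2 (2.56), Hoxd4 (1.61) and Hoxb1 (1.54) rose, and Pou2f2 (-2.50; adjusted p = 0.0597 without cKO 1), Zfhx3 (-2.15), Zfhx2 (-1.90) and Mir99ahg (-1.69; 0.0777 without control 2) fell.

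In neural tube progenitor-like cells 72 of 8564 genes changed, 31 up and 41 down (13 without control 2, 187 without cKO 1, 339 without cKO 2, 16 with the replicate block, 39 with thinned counts, 121 with doublets kept, 382 with no gene filter), and by DESeq2 50 rose and 31 fell. Sox9 fell (-1.68), as did Ttyh1 (-1.65; 0.180 without control 2), Cdh11 (-1.47; 0.172 without control 1, 0.0659 without control 2) and Elavl3 (-1.35; 0.313 without control 2). Ddit4 (1.86; 0.118 without control 1), Bnip3 (1.56; 0.112 and 0.249 without control 1 and 2), Fgfbp3 (1.12; 0.172, 0.257 and 0.137 without control 1, control 2 and cKO 1) and Trim71 (1.02; 0.0967 and 0.257 without control 1 and 2) rose. In leukocyte-like cells 266 of 8944 genes changed, 111 up and 155 down (83 without control 1, 409 without control 2, 156 with DESeq2, 141 with the stricter cell filter, 541 with doublets kept, 668 with no gene filter, 840 with the replicate block). The interferon-inducible Ifi202b was counted 277 times in control and 0 times in cKO, at least 116-fold lower against a floor of 3 counts over the group. A strain difference carried with the floxed alleles could also give this value and was not tested. Plac8 (1.32), Csrp2 (1.24), Cd9 (1.18) and Eif3j1 (1.46; 0.0677 without control 1) rose, and Tgfbi (-2.07), Fcna (-1.61; 0.153 without control 1) and Timd4 (-1.56; 0.210, 0.0713 and 0.135 without control 1, control 2 and cKO 1) fell. Values after a left-out library are adjusted p.

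Ubb (ENSMUSG00000019505, chromosome 11, 62551171 to 62553213) rose in all 8 classes tested, by 2.80 to 3.18 on the log2 scale. Of 6988 genes tested in all 8 classes, 16 changed the same way in each. Among them Ubb, the translation factor Eif4a1, Aurkaip1, Rpl26 and the glycolytic enzyme Pgam1 rose, and Hnrnpa0, Dync1i2, the predicted genes Gm8797 and AC149090.1, and 6 mitochondrial genes fell. They were named because of this pattern, after their values had been seen. Fold changes had the same sign in all 8 classes for 2317 genes, where independent signs would give 54.6; the classes share libraries, so the signs are not independent. Correlations of fold changes across genes between classes ranged from 0.445 to 0.775. Reads of Ubb, Rpl26 and Gm8797 may be shared with near-identical copies, so their levels are uncertain.

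**Figure D5:**
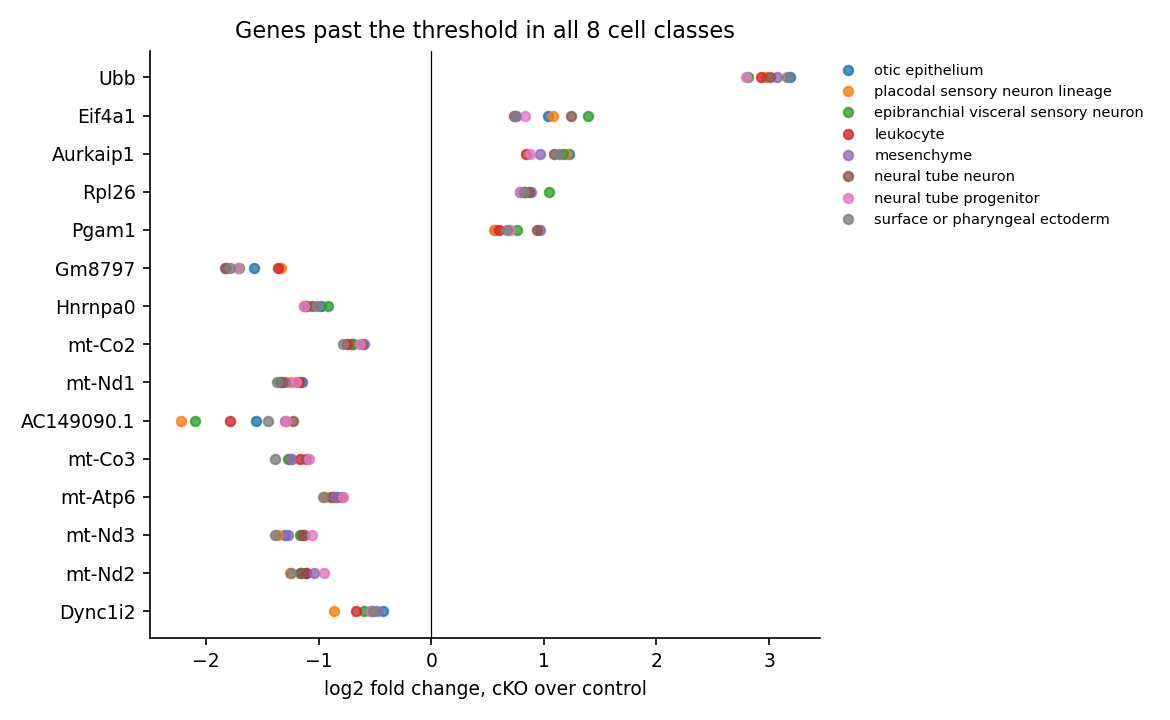
Log2 fold changes (cKO over control) of genes among the 16 that changed the same way in all 8 classes, with a point for each class. Ubb is near 3 in each class, between 2.80 and 3.18.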

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

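The tests of library batches, and of pattern genes in which no near-identical copy was found, were chosen only after the results they weigh had been seen. For the other tests only the bounds were set before their values were seen, since the shared clusters and reference classes that some of them use were chosen after the data had been seen.

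Of 34 named genes given here, 23 had a genotype effect that differed between otic and neuron lineage cells by the edgeR interaction test. Over all genes tested the count was 2463 of 15150. Most named genes were chosen for large fold changes in either class, which favours such a difference. Values are otic minus neuron lineage log2 changes. More positive in otic cells were Sfrp2 (1.51), Mt1 (0.86), Pcolce2 (1.82), Hs3st1 (0.88), C1ql3 (4.85), Sncg (1.99), Epha5 (2.49), Thsd7a (2.40), Syn2 (2.42) and Armh4 (2.27). More negative in otic cells were Tbx2 (-0.61), Oc90 (-1.98), Itga4 (-1.51), C1qtnf12 (-1.27), Hsd11b2 (-2.32), Otol1 (-0.68), Wfdc3 (-2.75), Gal (-4.36), Spp1 (-2.35), Zfp503 (-2.26), Lrrc10b (-2.59), Lfng (-1.29) and Igf2 (-1.98). No explanation was tested for single genes.

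The 16 genes that changed the same way in all 8 cell classes, led by Ubb, call for caution. Reads shared between near-identical copies fit part of them. Of the 9 nuclear genes that could be searched, 33.3% (Ubb, Rpl26 and Gm8797) hold such sequence, against 5.52% of other genes (one-sided Fisher's exact p = 0.0111). The other 6 of the 9 shared none of the words searched. That search used spaced, exactly matching words of annotated transcripts and could miss copies with mismatches. It therefore does not exclude shared reads for those 6. Free RNA from otic cells does not account for these genes as a set. Their median ratio of leukocyte to otic CPM in control was 1.17, not the small value that background would give. The genes had to be measured in every class, however, which favours a ratio near that value. The ratio was lower for Ubb (0.522), Gm8797 (0.486) and Hnrnpa0 (0.465), so the median does not decide for single genes. A difference between library batches that follows genotype cannot be told apart from genotype, since no batch is recorded. Otic fold changes correlated across genes at 0.731 with the reference classes, but differences between libraries of one genotype correlated at 0.481 and 0.631 in the same way, so this value does not decide it. A strain difference near the floxed alleles, or an effect of the knockout on neighbouring tissue, stays open and was not tested.

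The fall of neuronal differentiation genes in the neuron lineage, with all 20 members lower, was weighed against 2 accounts. Loss of the late clusters 17 and 21 does not by itself account for it. Within cluster 1, which both genotypes share, the list median was -1.12 (quartiles -1.27 and -0.62), past the bound set beforehand, and 14 of 19 members fell. The mix within cluster 1 may differ, however. At resolution 2, a neuron lineage cluster led by Hmx1, Pou4f1 and Fgf10 held 164 and 118 control and 26 and 28 cKO cells. Another, led by Wfdc3, held 77 and 61 control and 99 and 153 cKO cells. A lower share of later cells inside cluster 1 is therefore not excluded. A shift shared by all cell types is excluded, because the same genes had a median of -0.082 in neural tube neuron-like cells (quartiles -0.27 and 0.31). In epibranchial neuron-like cells the list also fell, in 15 of 20 members (median -0.76), so a shift shared by placodal neurons is not excluded. The clusters of that class also differed by genotype, with cluster 8 at 40.1% of control and 64.9% of cKO cells, so composition enters this median. Delayed maturation of these neurons, and a small difference in embryo stage between the groups, were not tested and stay open.

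The fall of nonsensory and otolith genes in otic cells, with 9 of 11 members lower, rests on less. The missing otic clusters alone may account for part of it, since the list median was -0.82 within the shared otic clusters and -2.05 in the whole class, a value between the bounds set beforehand. The shared clusters were pooled and their mix differed by genotype (cluster 4 was 7.56% of control and 19.4% of cKO otic cells), so -0.82 is not free of composition. A shift shared by all cell types is likewise undecided, with 7 of the 9 called members that fell beyond the 99th percentile (0.79) of the shift in the reference classes. Loss of ventral and nonsensory cells, and lower expression within the remaining cells, cannot be told apart here.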

How the results depend on the processing

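The fits on shared clusters only and beyond the reference classes were chosen after the data had been seen; all other alternatives were planned. Where a library was left out, the lone library of its group was assumed to vary like the other group.

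In otic cells the count of changed genes stayed within 1.5 times the 6192 of the report under each alternative set down beforehand, from 4215 to 6983. Tbx3 in otic cells and over all kept cells, and Tbx2 in otic cells, fell and passed with DESeq2, RLE factors, the replicate block and each library left out, the alternatives tabulated for them, though within the shared otic clusters Tbx3 did not pass (-0.39, adjusted p = 0.0847). The class shares stayed at 0 changed by edgeR under each alternative, with 0 at an unadjusted p under 0.05 in the reported fit.

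Counts that moved further include these, and the cause was not tested. Over all kept cells (4679) leaving out a library gave 477 to 3066. In the neuron lineage (4922) it gave 3053 to 5355, and in the other classes together (4832) 1794 to 5367. In those classes DESeq2 gave 2595, equal cells per library 2945 and no gene filter 8666. In single classes, equal cells gave 48 in ectoderm, against 643. The replicate block gave 840 in leukocytes (266), 1119 in ectoderm and 16 in neural tube progenitors (72). No gene filter gave 921 in neural tube neurons (124), 668 in leukocytes, 382 in neural tube progenitors, 1235 in mesenchyme (642) and 1344 in ectoderm, and doublets kept gave 541 in leukocytes and 121 in neural tube progenitors. The interaction (2463) ranged from 1482 to 3136 with a library left out. Tbx2 over all kept cells stood at -0.47 with RLE factors, where it did not pass (adjusted p = 0.0548), and at -0.71 to -0.28 with a library left out. The otic cluster shares (10) numbered 6 at resolution 0.5, 17 at resolution 2, 4 to 8 with a library left out and 1 with the replicate block; the clusters themselves differ between resolutions.

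Of the otic gene lists (11), 0 passed with camera and an estimated correlation, 7 with fry and 6 in the shared clusters only. Of the neuron lineage lists (7), 0 passed with an estimated correlation, 0 with fry and 8 to 11 with a library left out. Beyond the reference classes 447 otic and 1356 neuron lineage genes passed, a stricter question than change alone.

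The balance of directions depended on the processing: 51.9% of otic calls were up in the report and 59.4% with DESeq2, and over all kept cells 54.8% in the report, 47.5% with no gene filter and 47.2% without cKO 2. In mesenchyme 332 rose and 310 fell in the report, and 216 and 90 with DESeq2. The interaction turned from 1297 more positive and 1166 more negative in otic cells to 1206 and 1293 with RLE factors, 1538 and 1611 with no gene filter, 785 and 814 without cKO 1 and 730 and 752 without cKO 2.

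Among 248 values of named genes, 0 changed sign while called under any alternative set down beforehand. DESeq2 lost 25 calls and gained 2, equal cells lost 13, thinned counts lost 9, and leaving out a library lost 57 and gained 11 of 989 comparisons.

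The shared replicate numbers do not pair the libraries: deviations of same-numbered libraries correlated across genes at -0.039 over all kept cells, 0.035 in otic cells and -0.016 in the neuron lineage. With the replicate number as a block, 3900 genes passed over all kept cells, 6451 in otic cells, 4636 in the neuron lineage and 6861 in the other classes, with 10 otic and 7 neuron lineage lists, and 0 class shares by edgeR. The interaction already holds the library as a block.

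Small changes were often missed: in simulated data 47.8% of otic genes and 19.0% of neuron lineage genes changed by a log2 fold of 0.5 were recovered.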

Other observations

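The gene list tests in the other classes, the look at sex-linked genes and the comparison of libraries within each genotype were not planned and were chosen after the main results had been seen.

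Lists also changed in the cells around the vesicle, many of them in the same direction as in otic or neuron lineage cells. The glycolysis and hypoxia list passed upward in each of the 6 other classes tested by camera with a preset correlation, and in none with an estimated one. In some classes few single members passed. The camera adjusted p was 3.37e-08 in mesenchyme (11 of 13 members up, median 0.97), 2.71e-06 in ectoderm (7 of 13), 1.70e-05 in neural tube progenitors (3 of 12), 4.70e-05 in neural tube neurons (1 of 13), 2.17e-04 in the epibranchial class (9 of 13) and 0.00192 in leukocytes (1 of 11). Adjusted over the list alone, 12, 11, 11, 10, 12 and 4 members rose in the same order. With an estimated correlation the adjusted p was 0.781, 0.769, 0.960, 0.986, 0.823 and 0.822. In otic cells the same list passed (0.0429), but not with an estimated correlation (0.914) nor without control 1 (0.0538), control 2 (0.116) or cKO 1 (0.666). Hedgehog genes fell in mesenchyme, with 2 of 9 members down and 8 down when adjusted over the list alone (median -1.06, adjusted p = 2.42e-04, and adjusted p = 0.781 with an estimated correlation).

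In the epibranchial class, neurons of a neighbouring placode, neuronal differentiation genes fell in 15 of 20 cases (median -0.76, camera adjusted p = 2.56e-04), and neuroblast specification (9 of 16 up, 0.00239), Notch (9 of 16, 0.00105), retinoic acid (4 of 7, 0.00614), S phase (6 of 18, 0.00152), G2 and M (9 of 18, 0.00341) and epithelial junction genes (4 of 9, 0.00155) rose. The neuronal differentiation, Notch, S phase, G2 and M and epithelial junction lists moved the same way in the neuron lineage. Composition enters the epibranchial lists, since cluster 8 was 40.1% of control and 64.9% of cKO cells of the class and cluster 12 was 59.9% and 35.1%. With an estimated correlation the adjusted p of these lists ranged from 0.673 to 0.823, and without control 1 or control 2 only 0 and 3 single genes of this class passed by edgeR. Retinoic acid genes rose in neural tube neurons (3 of 6, adjusted p = 0.00815, and adjusted p = 0.986 with an estimated correlation), as did prosensory genes in ectoderm (3 of 11, adjusted p = 0.0369, and adjusted p = 0.769 with an estimated correlation). The neuroblast list passed upward in neural tube progenitors (adjusted p = 0.00265, and adjusted p = 0.960 with an estimated correlation), with 0 of 10 single members passing by edgeR and 4 over the list alone.

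Sex-linked genes differed between libraries. Xist, expressed from the inactive X chromosome, stood at 361, 293 and 293 CPM in control 1, control 2 and cKO 1 and at 0.0547 CPM in cKO 2. The Y-linked Ddx3y stood at 17.4, 17.3, 17.1 and 29.0 CPM in the same order, and Eif2s3y at 29.9, 35.02, 31.4 and 58.4 CPM. The cKO 2 library thus held cells with next to no Xist, and the others held both Xist and Y-linked transcripts.

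Libraries of the same genotype also differed together across classes. Over 6995 genes, the difference between the control libraries correlated at 0.481 between otic cells and the reference classes (SD in otic cells 0.133), and that between the cKO libraries at 0.631 (SD 0.212). For cKO against control the correlation was 0.742 (SD 0.334).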
